A study of Mus musculus with 6 samples.

How the data were processed

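RNA-seq was done on 6 libraries of mouse ESCs, 3 untreated (day −2) and 3 at day 2, after a NaB treatment (0.5 mM) of 2 days and 2 further days in TSC medium. Per the labels' protocols, total RNA was extracted with a commercial kit and libraries were made with the NEBNext Ultra kit, a kit that does not mark strand. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.5a and HTSeq 0.13.5 and the genome build mm10, and give no role or order for them. The gene annotation, the strand setting and the handling of reads with several matches are not given in the sources used here. The authors' table gives one expected or estimated count per gene and library, since 19.8 to 22.4% of the nonzero values in a library carry decimals of up to 2 places and the rest are whole. How the decimals arose is not given, and where near-identical copies carry them, as the Zscan4 and Usp17l families do, levels of single copies are uncertain. Counts of overlapping or antisense genes are uncertain too, since no strand was kept.

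The table held 55304 genes, of which 27908 were at 0 in all 6 libraries. Library totals were 22.3 M, 27.2 M and 16.4 M for untreated replicates 1, 2 and 3 and 16.7 M, 18.7 M and 23.9 M for treated replicates 1, 2 and 3. The values were rounded to whole numbers, and genes with enough counts for the group sizes were kept with filterByExpr of edgeR (minimum count 10, minimum total 15), which left 15360. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on TMM-normalised counts with group as the only term, with Benjamini-Hochberg adjustment over the 15360 genes and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. Normalised CPM are the deposited values over the library size times the TMM factor (0.917 to 1.16), and log2 CPM for correlations and principal components used a prior count of 2. With 3 libraries per group the p-values measure the spread between libraries only, since the labels do not say whether replicates were separate cultures. Correlations and exact tests on library shares are descriptions, as 3 against 3 cannot give a permutation p under 0.1.

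Gene lists, 30 in number, were tested with camera of limma 3.58.1 on the edgeR fit with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry were run beside it. Per list the text gives the members past the adjusted p over all genes and the same after adjustment over the list alone. The test, the lists, the named genes and the alternatives were chosen before the data were examined, except where stated. The genes named are 11 sentinel genes whatever their result, the 8 higher and the 8 lower genes with the largest change among called genes with at least 10 CPM in the higher group, the same direction in every pair of libraries and an established symbol, and up to 4 called members per list with the largest change and at least 1 CPM. Members named because a list had 5 or fewer on one side, or because their call was lost without a library, were chosen after their values were seen. A gene at 0 in one group is compared with a floor of 3 counts over the group, and a gene with 1 to 3 counts is given as a ratio with an exact 95% interval, both of which cover counting error only.

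Gene positions come from GENCODE M21 on GRCm38 (mm10), matched by symbol for 98.8% of the tested genes, and are given as chromosome, start and end counted from 1. The same fit was tested on simulated counts for 14434 genes drawn from the real means and library sizes, with 200 genes changed. It called 8.89% of genes changed by 0.5 on the log2 scale, 72.3% of those changed by 1, 93.9% by 2 and 100% by 3, and 8 of its 138 calls (5.80%) were false. It called 5 of 5 lists whose 15 members were all raised by 1 on the log2 scale, and 0 of 25 that were not moved. Lists with smaller or mixed changes were not simulated. The simulated genes were drawn independently of each other, so this does not test lists whose members vary together. The simulation also changed far fewer genes than the 7259 called in the data, so its shares need not hold there. On the real libraries the preset list test called 4 to 12 of the 30 lists in each of the other 9 splits into 3 and 3. Each side of those splits held libraries of both groups in unequal number. Part of the group difference stayed in them, so these calls give no rate of false calls.

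Alternatives were DESeq2 size factors, library sizes alone, no filter on low counts, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a test against a fold of 1.5, the replicate number as a block, leaving out mitochondrial and histone genes, and leaving out each library in turn. Leaving out mitochondrial and mitochondrial-like genes, and leaving out the 2 treated libraries with a high mitochondrial share, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.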

Results

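RNA was measured by sequencing in 6 libraries of mouse embryonic stem cells (ESCs) of the 129/Ola strain, which stand for 2 groups of 3. The first group was untreated and was taken at day −2. The other group was kept for 2 days in ESC medium with 0.5 mM sodium butyrate (NaB), an inhibitor of several histone deacetylases, and then for 2 days in medium for trophoblast stem cells (TSCs), the self-renewing precursors of the placenta, and was taken at day 2. The untreated libraries held 22.3 M, 27.2 M and 16.4 M counts, and the treated libraries held 16.7 M, 18.7 M and 23.9 M. Between 20404 and 22625 genes per library had a count above 0. The table listed 55304 genes, of which 15360 had enough counts to be tested. Levels are given as normalised CPM, counts scaled to a common library size, with mean ± SD over the 3 libraries of a group, and fold changes as log2 of treated over untreated. Mitochondrial transcripts took 11.6%, 9.65% and 10.7% of the counts in the untreated libraries and 17%, 7.08% and 21% in the treated ones, so that treated replicates 1 and 3 stood above the other 4 libraries (exact permutation test, two-sided, p = 0.4, where the smallest possible p is 0.1). The groups were separate in the first principal component, which carried 74.1% of the variance, and the Pearson correlation of log2 CPM was 0.979 to 0.992 among untreated libraries, 0.973 to 0.978 among treated ones and 0.908 to 0.928 between the groups.

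The comparison asks how the transcriptome of ESCs changed after a pulse of NaB and a change to TSC medium. No library of TSCs was among the 6, so how near the cells came to TSCs could not be measured. After the treatment, the genes of naive pluripotency and of the response to leukaemia inhibitory factor (LIF) were lower, and genes of the formative epiblast, of the 2-cell-like state, of epithelia and of fibroblasts were higher. With an estimated correlation between genes the rises of these 4 lists did not pass the list test (adjusted p = 0.0782, 0.0733, 0.455 and 0.0733). Of the 16 fibroblast genes listed, only 9 were high enough to test. Esrrb, a nuclear receptor that sustains naive pluripotency, fell from 593 ± 18.5 to 78.7 ± 6.08 CPM. Fgf5, a growth factor that marks the postimplantation epiblast, rose from 0.702 ± 0.584 to 23 ± 1.46 CPM. The TSC regulator Cdx2 rose from 0.60 ± 0.65 to 2.55 ± 0.251 CPM, a low level, and its call was lost without untreated replicate 1 or treated replicate 1, 2 or 3 (adjusted p = 0.098, 0.0952, 0.0617 and 0.0639). Eomes stood at 3.46 ± 1.14 and 5.29 ± 0.995 CPM and did not pass the test (adjusted p = 0.0982), but passed it without untreated replicate 1 (adjusted p = 0.0388). Pou5f1, the core pluripotency factor Oct4, fell but stayed at 349 ± 54.7 CPM, and Sox2 was at 294 ± 7.2 CPM.

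**Figure D1:**
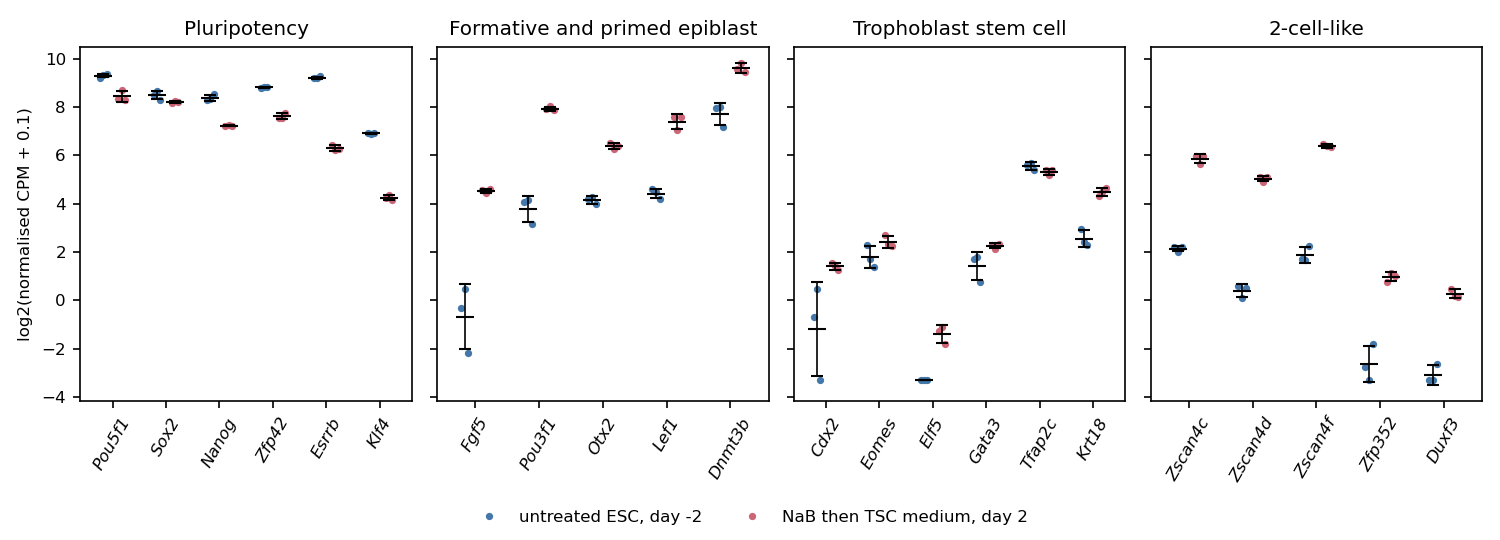
Normalised CPM of 22 genes in each of the 6 libraries, plotted as log2(CPM + 0.1), with untreated ESCs in blue and cells after NaB and TSC medium in red. Points are libraries, and bars are the mean and SD of the plotted log2 values for 3 libraries. Esrrb went from 593 ± 18.5 to 78.7 ± 6.08 CPM. Elf5 was at 0 in the untreated libraries.

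Naive pluripotency genes, which mark ESCs that resemble the preimplantation epiblast, fell as a group. Of the 20 tested members, 17 fell and 1 rose (2 higher and 17 lower when adjusted over the list alone). The naive pluripotency list had a median log2 fold change of −1.52 and a camera adjusted p of 5.67e-26 (adjusted p = 0.00888 with an estimated correlation). Jam2, a junctional adhesion molecule, had a log2 fold change of −3.47 (SE 0.14) with an adjusted p of 2.04e-07 in edgeR's quasi-likelihood test. Esrrb (chromosome 12, 86361117 to 86521628) changed by −2.91 (SE 0.11, edgeR adjusted p = 1.82e-07), and Tfcp2l1, a factor downstream of LIF, changed by −2.86 (SE 0.12, edgeR adjusted p = 2.70e-07). Klf4, a Krüppel-like factor of the naive network, fell from 120.4 ± 2.13 to 18.9 ± 1.46 CPM. Nanog (chromosome 6, 122707489 to 122714633), the homeodomain factor of the inner cell mass, fell from 333 ± 31.9 to 149 ± 2.61 CPM, with a log2 fold change of −1.16 (SE 0.10, edgeR adjusted p = 2.04e-05). Zfp42 (chromosome 8, 43295063 to 43306980), also called Rex1, fell from 448 ± 9.36 to 198 ± 16.4 CPM, with a log2 fold change of −1.18 (SE 0.10, edgeR adjusted p = 1.66e-05). The member that rose was Sox15, a Sox factor, at 0.66, a call that was lost without untreated replicate 2 or 3 or treated replicate 1 or 3 (adjusted p = 0.0713, 0.0992, 0.078 and 0.121).

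The general pluripotency list was meant to hold genes shared by naive and primed cells, which was not tested for each member. Of the 15 tested, 5 fell and 2 rose (2 higher and 6 lower when adjusted over the list alone). The general pluripotency list had a median log2 fold change of −0.29 and a camera adjusted p of 0.0184 (adjusted p = 0.423 with an estimated correlation). Gdf3 (−3.23) and Tdh (−2.55) lay far below that median, and the list was not tested without them. Its call therefore does not show a fall of most members. Pou5f1 (chromosome 17, 35506018 to 35510772) fell from 628 ± 30.5 to 349 ± 54.7 CPM, with a log2 fold change of −0.85 (SE 0.13, edgeR adjusted p = 4.17e-04). Sox2 (chromosome 3, 34650405 to 34652461), its partner factor, was at 359.7 ± 43.3 and 294 ± 7.2 CPM and did not pass the test (log2 fold change −0.29, SE 0.11, edgeR adjusted p = 0.0532). It passed without untreated replicate 3 or treated replicate 2 (adjusted p = 0.0138 and 0.0309), and also without a filter on low counts (adjusted p = 0.02), with the DESeq2 Wald test (adjusted p = 0.0362) and with limma-voom (adjusted p = 0.0444). Gdf3, a TGF-beta family ligand, fell from 63.9 ± 8.11 to 6.8 ± 1.1 CPM. Tdh, the threonine dehydrogenase of mouse ESCs, fell from 117 ± 13.4 to 20 ± 3.58 CPM. L1td1, an RNA-binding protein, fell from 992 ± 12.3 to 506 ± 31.6 CPM. The fifth gene that fell was Sall4 (−0.41), and those that rose were Dnmt3l, a cofactor of de novo DNA methylation (0.72), and Trim71 (0.42). The Sall4 call was lost without untreated replicate 1 or 2 or treated replicate 1 or 3 (adjusted p = 0.138, 0.137, 0.0808 and 0.121). The Trim71 call was lost without untreated replicate 1 or 3 (adjusted p = 0.0556 and 0.0862).

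The LIF and STAT3 response list, whose genes are induced by or carry the signal of the cytokine that keeps mouse ESCs naive, fell. It shares Klf4 and Tfcp2l1 with the naive list, so the 2 results are not independent. Of its 11 tested members, 10 fell and 1 rose (1 higher and 10 lower when adjusted over the list alone). The LIF and STAT3 response list had a median log2 fold change of −2.23 and a camera adjusted p of 1.00e-20 (adjusted p = 0.0154 with an estimated correlation). Socs3, the feedback inhibitor of STAT3, was among the most decreased genes and fell from 120.2 ± 6.31 to 6.85 ± 0.343 CPM (log2 fold change −4.13, SE 0.11, edgeR adjusted p = 3.72e-08). Bcl3, a nuclear IkappaB protein, fell from 77.5 ± 4.54 to 7.95 ± 3.39 CPM. The member that rose was the kinase gene Pim1 (1.46).

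Formative and primed epiblast genes, which mark the epiblast around and after implantation, rose together. Of the 13 tested, 11 rose and 1 fell (11 higher and 1 lower when adjusted over the list alone). The formative and primed epiblast list had a median log2 fold change of 1.71 and a camera adjusted p of 3.50e-13 (adjusted p = 0.0782 with an estimated correlation). Fgf5 (chromosome 5, 98254184 to 98277030) had the largest increase among the named genes of this list (log2 fold change 4.89, SE 0.38, edgeR adjusted p = 9.49e-06), which was 5.67 without untreated replicate 2. Pou3f1, the POU factor Oct6 of the primed state, rose from 14.3 ± 4.66 to 243 ± 14.6 CPM (log2 fold change 4.08, SE 0.22, edgeR adjusted p = 9.85e-07). Lef1, a nuclear effector of Wnt signals, rose from 21.3 ± 2.87 to 171 ± 35 CPM. Otx2, a homeobox factor needed to enter the formative state, rose from 17.7 ± 1.79 to 83.5 ± 6.58 CPM. The member that fell was Etv1, an ETS factor (−0.65), a call that was lost without untreated replicate 1 (adjusted p = 0.0776). Fibroblast marker genes rose in the same comparison, as given with the other lineages.

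Trophoblast stem cell genes were tested as the state the treatment was aimed at. Of the 19 tested members, 10 rose and 3 fell (11 higher and 3 lower when adjusted over the list alone), and the list was not called as a whole (median log2 fold change 0.74, camera adjusted p = 0.0764). It became a call without untreated replicate 1 or 2 (adjusted p = 0.0423 and 0.0316), while with an estimated correlation the adjusted p over all libraries was 0.579. Cdx2 (chromosome 5, 147300805 to 147307270), the caudal homeobox factor of trophectoderm, had a log2 fold change of 1.97 (SE 0.69, edgeR adjusted p = 0.0377) over 46 counts in the untreated and 151 counts in the treated libraries. Untreated replicate 3 had 0 counts of Cdx2. The fold change was 3.16 without untreated replicate 2 (adjusted p = 0.00974) and 1.45 without untreated replicate 3 (adjusted p = 0.0261). The Cdx2 call was lost without untreated replicate 1 or treated replicate 1, 2 or 3 (adjusted p = 0.098, 0.0952, 0.0617 and 0.0639). Eomes (chromosome 9, 118478212 to 118486132), a T-box factor of TSCs, did not pass the test (log2 fold change 0.60, SE 0.27, edgeR adjusted p = 0.0982), but passed it without untreated replicate 1 (adjusted p = 0.0388) and with the replicate number as a block (adjusted p = 0.0497). Elf5 (chromosome 2, 103411688 to 103450989), an ETS factor that stays methylated and silent in ESCs, had 0 counts in the untreated libraries and 17 in the treated ones, at least 6.17-fold higher against a floor of 3 counts over the group, and was too low to be tested. Gata3 (chromosome 2, 9857078 to 9890034), a GATA factor of trophectoderm, was at 2.7 ± 0.991 and 4.7 ± 0.361 CPM (log2 fold change 0.77, SE 0.29, edgeR adjusted p = 0.0513), and Tfap2c (chromosome 2, 172549593 to 172558622), the AP-2 gamma factor, was at 47 ± 5.15 and 39.8 ± 3.55 CPM (log2 fold change −0.24, SE 0.12, edgeR adjusted p = 0.124). Neither of these 2 genes passed the test, though Tfap2c did without untreated replicate 3 (adjusted p = 0.0357). Gata3 passed without a filter on low counts (adjusted p = 0.0483), with a filter of 1 CPM (adjusted p = 0.0464) and with limma-voom (adjusted p = 0.0426). It also passed without mitochondrial and histone genes (adjusted p = 0.0443) and without mitochondrial and mitochondrial-like genes (adjusted p = 0.0432). Krt18, a keratin of simple epithelia, rose from 5.88 ± 1.51 to 22.2 ± 2.65 CPM. Krt18, Krt8 and Cldn4 are also in the epithelial list, so the results of these lists are not independent. The X-linked homeobox gene Esx1 rose from 3.53 ± 0.835 to 12.4 ± 4.46 CPM. Among other members that rose, the Gata2 call was lost without untreated replicate 2 or 3 or treated replicate 1, 2 or 3 (adjusted p = 0.0687 to 0.112). The Tfap2a call was lost without untreated replicate 1 or 2 or treated replicate 1 or 3 (adjusted p = 0.0869 to 0.127). Rhox5 lost its call without untreated replicate 1 or 2 or treated replicate 1 (adjusted p = 0.0824 to 0.11). Ets2 lost its call without untreated replicate 2 (adjusted p = 0.0555). The members that fell were Wnt7b, a Wnt ligand of the placenta (from 5.11 ± 2.11 to 1.75 ± 0.417 CPM), the ligand gene Bmp4 (−1.34) and Sox21 (−1.25), whose call was lost without untreated replicate 1 or 2 (adjusted p = 0.0503 and 0.0739).

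Genes of differentiated trophoblast, the lineages that build the mature placenta, were often too low to test. Of 31 listed genes 14 could be tested, 6 of them rose and 2 fell (7 higher and 2 lower when adjusted over the list alone), and the list was not called (median log2 fold change 0.89, camera adjusted p = 0.0664). It became a call without untreated replicate 1 or 2 or treated replicate 2 (adjusted p = 0.0484, 0.037 and 0.0421), while with an estimated correlation the adjusted p over all libraries was 0.496. Hand1, a bHLH factor of giant cells, rose from 0.725 ± 0.467 to 8.33 ± 1.02 CPM (log2 fold change 3.43, SE 0.36, edgeR adjusted p = 5.36e-05), which was 4.11 without untreated replicate 2. Dlx3, a homeobox factor of the labyrinth, rose from 1.31 ± 0.0939 to 13.5 ± 3.8 CPM (log2 fold change 3.37, SE 0.27, edgeR adjusted p = 9.95e-06). The gelatinase gene Mmp9 rose from 1.1 ± 0.27 to 6.52 ± 1.3 CPM. Flt1, a receptor for vascular endothelial growth factor, rose from 0.866 ± 0.232 to 4.22 ± 0.797 CPM. Gcm1 also rose, a call that was lost without untreated replicate 2 or 3 or treated replicate 1 or 3 (adjusted p = 0.0559, 0.0527, 0.106 and 0.0936). The Ovol2 rise lost its call without untreated replicate 1 or 3 or treated replicate 2 (adjusted p = 0.0684, 0.0618 and 0.0785). The members that fell were the imprinted genes Phlda2 (−1.25) and Slc38a4 (−0.81).

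Genes of the 2-cell-like state, which in normal development are expressed at the first activation of the embryonic genome, had the highest median of the 30 lists. All 15 tested members rose (15 higher and 0 lower when adjusted over the list alone). Members near 0 before treatment, such as Duxf3 and Zfp352, could pass the count filter only through the treated libraries. Such genes could not have been called lower, so the filter favoured this count. The 2-cell-like list had a median log2 fold change of 4.25 and a camera adjusted p of 9.48e-30 (adjusted p = 0.0733 with an estimated correlation). Zscan4d (chromosome 7, 11161374 to 11166159), a zinc finger gene active in that state, rose from 1.22 ± 0.233 to 32.8 ± 2.66 CPM (log2 fold change 4.75, SE 0.18, edgeR adjusted p = 1.82e-07). Zfp352, a zinc finger gene active at the same stage, rose from 0.0765 ± 0.0952 to 1.87 ± 0.238 CPM (log2 fold change 4.75, and 4.03 without untreated replicate 2 and 6.13 without untreated replicate 3). Duxf3, the homeobox gene that switches the programme on, went from 1 count to 65 counts, a ratio of 70.8 with a 95% counting interval of 12.3 to 2839. The fitted log2 fold change of Duxf3 was 5.68, and 5.05 without untreated replicate 2 and 7.58 without untreated replicate 3. The Zscan4 and Usp17l genes are near-identical copies whose counts held decimals, so levels of single copies are uncertain, while the summed counts of the 9 Zscan4 members rose from 18.8 ± 2.84 to 343 ± 25.6 CPM. As such copies may share reads, the 15 members are not separate observations. The camera p at the preset correlation may therefore be too small.

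Germline genes, many of them silenced by DNA methylation in somatic cells, also rose. Of the 19 tested, 12 rose and 2 fell (12 higher and 3 lower when adjusted over the list alone). The germline list had a median log2 fold change of 0.68 and a camera adjusted p of 0.00674 (adjusted p = 0.496 with an estimated correlation). Sycp2, a component of the synaptonemal complex, rose from 5.36 ± 2.11 to 42.8 ± 12 CPM. Tex19.1, which restrains transposons, rose from 15.3 ± 5.28 to 81 ± 16.2 CPM. The testis-type paralogue Taf7l rose from 1.78 ± 0.0984 to 8.47 ± 1.3 CPM. The members that fell were Piwil2, a piRNA-binding protein (−0.71), and Rpl10l (−0.50). The Piwil2 call was lost without untreated replicate 3 or treated replicate 1 or 3 (adjusted p = 0.144, 0.116 and 0.155). The Rpl10l call was lost without treated replicate 3 (adjusted p = 0.0503).

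Markers of other lineages moved in both directions. Primitive endoderm genes, of the extraembryonic layer beside the epiblast, had 9 members that fell and 3 that rose among 18 tested (3 higher and 9 lower when adjusted over the list alone). The primitive endoderm list had a median log2 fold change of −0.36 and a camera adjusted p of 0.0396 (adjusted p = 0.294 with an estimated correlation). This call was also lost with a filter of 1 CPM and with limma-voom. The laminin gene Lama1 fell from 82.8 ± 14 to 13.8 ± 0.658 CPM. The endoderm factors Gata6 and Sox7 fell from 4.25 ± 1.13 to 0.775 ± 0.677 CPM and from 1.27 ± 0.288 to 0.139 ± 0.0804 CPM. Gata6 had a log2 fold change of −2.51, and −3.43 without treated replicate 1. Those that rose were Amn (1.34), Apob (1.38) and Dab2 (1.0). The Amn call was lost without untreated replicate 2 or 3 or treated replicate 1 or 2 (adjusted p = 0.117, 0.0795, 0.0781 and 0.054). Among 12 neuroectoderm genes, 6 fell and 2 rose (2 higher and 6 lower when adjusted over the list alone). The neuroectoderm list had a median log2 fold change of −1.22 and a camera adjusted p of 0.0184 (adjusted p = 0.429 with an estimated correlation). Without a filter on low counts the median of 17 members was 0.58, opposite in sign to the test. Neurod1, a proneural bHLH factor, fell from 65 ± 4.95 to 14.5 ± 5.54 CPM. The early neural factor Sox1 fell from 5.36 ± 1.42 to 0.691 ± 0.166 CPM. Map2 (1.33) and Nes (0.69) rose. The Nes call was lost without treated replicate 1, 2 or 3 (adjusted p = 0.0842, 0.0707 and 0.0684). Of 10 primitive streak and mesoderm genes, 3 rose and 1 fell (3 higher and 1 lower when adjusted over the list alone). The primitive streak and mesoderm list had a median log2 fold change of 0.49 and a camera adjusted p of 0.375. The members called were Msx1 (3.44), Snai1 (1.16), Msx2 (0.65) and, as the one that fell, Cdx1 (−2.07). Cdx1 was −3.65 without treated replicate 2, and its call was lost without untreated replicate 1 or 2 or treated replicate 1 or 3 (adjusted p = 0.0866, 0.0869, 0.0845 and 0.0915). The Msx2 call was lost without untreated replicate 2 or 3 or treated replicate 1 or 3 (adjusted p = 0.151, 0.11, 0.0919 and 0.115). Markers of fibroblasts, which are used as feeders for such cultures, rose in 8 of 9 tested members and fell in 0 (8 higher and 0 lower when adjusted over the list alone). The other members of the 16 listed were too low to test. Lox and Col1a2, near 0 before treatment, could pass the count filter only through the treated libraries, so they could not have been called lower. Col3a1, Dcn, Lum and Postn of this list, a set chosen after the result was seen, were together at 0.223 ± 0.0676 CPM in untreated libraries. In treated libraries these 4 genes were together at 0.434 ± 0.175 CPM. The fibroblast feeder list had a median log2 fold change of 1.91 and a camera adjusted p of 4.12e-05 (adjusted p = 0.0733 with an estimated correlation). Without untreated replicate 1 the median of 11 tested members was 2.68. The collagen genes Col1a1 and Col1a2 rose from 2.81 ± 0.701 to 19.2 ± 3.04 CPM and from 0.291 ± 0.135 to 3.62 ± 0.404 CPM. Lox, a collagen cross-linking enzyme, rose from 0.108 ± 0.096 to 1.04 ± 0.31 CPM. The matrix gene Fbln2 rose from 0.575 ± 0.27 to 4.4 ± 1.08 CPM. Epiblast and 2-cell-like genes and Cdx2, Krt18 and Hand1 rose in the same 3 treated libraries as the fibroblast markers. The groups did not overlap for 97.8% of all genes called at an adjusted p under 0.05. A rise in the same libraries therefore does not show whether these rises share a source.

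**Figure D2:**
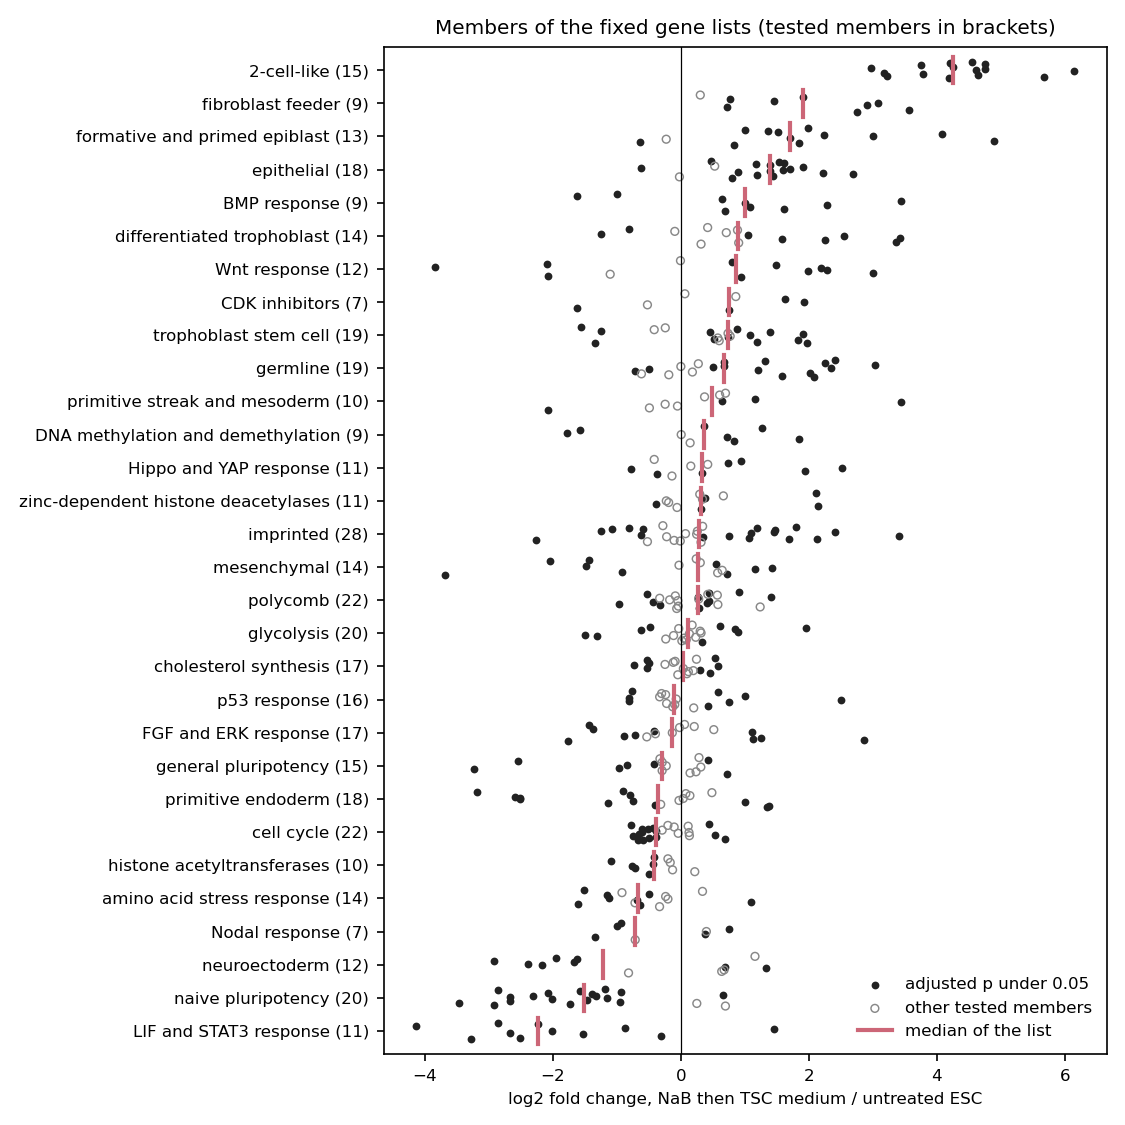
Log2 fold change of each tested member of the 30 gene lists, NaB then TSC medium over untreated ESCs, with lists ordered by their median. Filled points are members with an edgeR adjusted p under 0.05, open points are other tested members, and red bars are list medians, which run from −2.23 for the LIF and STAT3 response to 4.25 for 2-cell-like genes.

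Among chromatin regulators, the zinc-dependent histone deacetylases changed at the transcript level in both directions. Of their 11 genes, 4 rose and 1 fell (5 higher and 1 lower when adjusted over the list alone). The deacetylase list had a median log2 fold change of 0.32 and a camera adjusted p of 0.319. Hdac11 rose from 1.34 ± 0.0965 to 5.95 ± 1.12 CPM, Hdac9 rose from 0.946 ± 0.152 to 4.09 ± 0.461 CPM, Hdac6 had a log2 fold change of 0.37 (SE 0.10), and Hdac2, the member that fell, had one of −0.39 (SE 0.10). The Hdac2 call was lost with library sizes alone (−0.35, adjusted p = 0.0844). Hdac1 (chromosome 4, 129516104 to 129542713) rose from 193 ± 11.6 to 241 ± 29.9 CPM (log2 fold change 0.32, SE 0.11, edgeR adjusted p = 0.0421). The Hdac1 call was lost with library sizes alone (adjusted p = 0.102), without a filter on low counts (adjusted p = 0.102), and without untreated replicate 1, 2 or 3 or treated replicate 1 or 2 (adjusted p = 0.0718 to 0.129). Histone acetyltransferase genes had 6 members that fell and 0 that rose among 10 (0 higher and 6 lower when adjusted over the list alone). The histone acetyltransferase list had a median log2 fold change of −0.42 and a camera adjusted p of 0.0411 (adjusted p = 0.294 with an estimated correlation). This call was lost without treated replicate 2 (adjusted p = 0.051). Kat6b fell from 619 ± 93.3 to 291 ± 68.2 CPM. Kat2b fell from 63.3 ± 2.67 to 37.4 ± 3.66 CPM. Kat2a fell from 197 ± 21.5 to 120.2 ± 7.68 CPM.

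Genes of DNA methylation and demethylation split, with 5 of 9 higher and 2 lower (5 higher and 2 lower when adjusted over the list alone). The DNA methylation and demethylation list had a median log2 fold change of 0.37 and a camera adjusted p of 0.367. The de novo methyltransferase gene Dnmt3b rose from 217 ± 62.2 to 784 ± 106 CPM (log2 fold change 1.85, SE 0.20, edgeR adjusted p = 6.90e-05). The dioxygenase genes Tet1 and Tet2, which start demethylation, fell from 1072 ± 204 to 313 ± 10 CPM and from 261 ± 77.6 to 87.9 ± 18.4 CPM, while Tet3 rose from 17.9 ± 1.7 to 43.1 ± 0.136 CPM. Of 22 polycomb genes, 7 rose and 4 fell (9 higher and 4 lower when adjusted over the list alone). The polycomb list had a median log2 fold change of 0.27 and a camera adjusted p of 0.589. Suz12 rose from 271 ± 8.07 to 508 ± 15.5 CPM and Eed fell from 264 ± 12.7 to 135 ± 12.1 CPM, both core members of the repressive complex PRC2. Imprinted genes, expressed from a single parental allele, had 12 members that rose and 6 that fell among 28 (12 higher and 7 lower when adjusted over the list alone). The imprinted list had a median log2 fold change of 0.29 and a camera adjusted p of 0.193. This became a call without treated replicate 2 (adjusted p = 0.0395), with an adjusted p of 0.669 over all libraries at an estimated correlation. Magel2 rose from 3.82 ± 1.62 to 41.4 ± 3.84 CPM. Nnat rose from 7.82 ± 1.31 to 41.8 ± 5.53 CPM. The noncoding RNA gene H19 rose from 42.8 ± 14.1 to 189 ± 16.2 CPM. Grb10, an adaptor that restrains growth, fell from 244 ± 37.8 to 51 ± 7.23 CPM. Nnat and H19 counts held decimals, and the library kit does not mark strand, so reads of overlapping genes at such loci cannot be told apart.

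Genes that respond to signalling pathways moved in both directions. BMP response genes rose in 7 of 9 members and fell in 2 (7 higher and 2 lower when adjusted over the list alone). The BMP response list had a median log2 fold change of 1.01 and a camera adjusted p of 0.0184 (adjusted p = 0.455 with an estimated correlation). Id1 and Id3, inhibitors of bHLH factors, rose from 34.9 ± 4.07 to 106 ± 8.54 CPM and from 6.23 ± 1.54 to 30.6 ± 4.96 CPM. Msx1 rose from 0.435 ± 0.167 to 4.94 ± 0.483 CPM. Msx1 and Msx2 are also in the primitive streak and mesoderm list, so these results are not independent. The inhibitory genes Smad6 (−1.62) and Smad7 (−1.0) fell. Of 12 Wnt response genes, 7 rose and 3 fell (7 higher and 3 lower when adjusted over the list alone). The Wnt response list had a median log2 fold change of 0.87 and a camera adjusted p of 0.0751. It became a call without treated replicate 2 (adjusted p = 0.0104), with an adjusted p of 0.579 over all libraries at an estimated correlation. The feedback genes Nkd1 and Nkd2 rose from 1.56 ± 0.29 to 7.67 ± 1.94 CPM and from 2.3 ± 0.31 to 10.6 ± 3.9 CPM. Notum, a secreted Wnt deacylase, fell from 11.2 ± 4.69 to 0.763 ± 0.498 CPM, as did Sp5 (−2.09) and Cdx1 (−2.07). Cdx1 was −3.65 without treated replicate 2. Its call was lost without untreated replicate 1 or 2 or treated replicate 1 or 3 (adjusted p = 0.0866, 0.0869, 0.0845 and 0.0915). The log2 fold change of Notum was −3.85, and −4.57 without treated replicate 2. The FGF and ERK response had 4 higher and 6 lower of 17 (4 higher and 6 lower when adjusted over the list alone). The FGF and ERK response list had a median log2 fold change of −0.13 and a camera adjusted p of 0.354. The phosphatase gene Dusp4 rose from 12.3 ± 4.27 to 90.3 ± 2.81 CPM. Ccnd1, Spry2 and Spred1 fell by 1.76, by 1.44 and by 1.38 on the log2 scale. Nodal response genes had 2 higher and 3 lower of 7 (2 higher and 3 lower when adjusted over the list alone). The Nodal response list had a median log2 fold change of −0.71 and a camera adjusted p of 0.481. Skil (0.75) and Nodal itself (0.38) were higher, and Lefty2 (−1.34), Smad7 (−1.0) and Tdgf1 (−0.93) were lower. Hippo and YAP response genes had 5 higher and 2 lower of 11 (5 higher and 2 lower when adjusted over the list alone). The Hippo and YAP response list had a median log2 fold change of 0.33 and a camera adjusted p of 0.15. Ccn2, a matricellular target of YAP, rose from 31.2 ± 10.6 to 179.7 ± 5.3 CPM. The 2 lower members were Ccn1 (−0.78) and Amotl1 (−0.37). The Ccn1 call was lost without untreated replicate 1 or 2 or treated replicate 1 (adjusted p = 0.0771, 0.061 and 0.0589). The Amotl1 call was lost without untreated replicate 1, 2 or 3 or treated replicate 1 or 2 (adjusted p = 0.119, 0.0544, 0.0767, 0.105 and 0.0818).

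Epithelial genes rose, in 15 of 18 tested members against 1 that fell (15 higher and 1 lower when adjusted over the list alone). The epithelial list had a median log2 fold change of 1.39 and a camera adjusted p of 1.74e-05 (adjusted p = 0.455 with an estimated correlation). The claudin genes Cldn6 and Cldn7 of tight junctions rose from 10.4 ± 5.54 to 68.5 ± 11.5 CPM and from 1.42 ± 0.856 to 6.82 ± 1.29 CPM. Grhl2, a regulator of epithelial genes, rose from 34.9 ± 10.3 to 114 ± 5.92 CPM. The member that fell was Jup (−0.62), which encodes plakoglobin. The Jup call was lost without untreated replicate 1 or 2 (adjusted p = 0.0707 and 0.0633). Mesenchymal genes had 4 higher and 5 lower of 14 (5 higher and 5 lower when adjusted over the list alone). The mesenchymal list had a median log2 fold change of 0.27 and a camera adjusted p of 0.336. For them the median and the mean (−0.28) differed in sign, and the test had the sign of the mean. The intermediate filament gene Vim fell from 114 ± 13.2 to 27.8 ± 1.89 CPM. Zeb1, a repressor of epithelial genes, fell from 39 ± 8.12 to 14.4 ± 3.06 CPM.

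Cell cycle genes had 12 lower and 3 higher of 22 (3 higher and 13 lower when adjusted over the list alone). The cell cycle list had a median log2 fold change of −0.39 and a camera adjusted p of 0.0485 (adjusted p = 0.496 with an estimated correlation). This call was lost without untreated replicate 3 or treated replicate 1 or 3 (adjusted p = 0.0676, 0.0622 and 0.0718), with library sizes alone (adjusted p = 0.0807) and with a filter of 1 CPM (adjusted p = 0.0672). The mitotic kinase gene Plk1 fell from 267 ± 5.97 to 156 ± 13.3 CPM. Ccnb2 fell from 75.4 ± 3.21 to 45 ± 2.23 CPM. Bub1 rose from 108 ± 9.26 to 173 ± 20.3 CPM, as did Ccne2 (0.54) and Top2a (0.44). The Ccne2 call was lost without treated replicate 1 (adjusted p = 0.065). The Top2a call was lost without untreated replicate 2 (adjusted p = 0.0558). Of 7 CDK inhibitor genes, 3 rose and 1 fell (3 higher and 2 lower when adjusted over the list alone). The CDK inhibitor list had a median log2 fold change of 0.76 and a camera adjusted p of 0.589. Cdkn2a rose from 2.79 ± 0.756 to 10.4 ± 2.48 CPM, as did Cdkn2b (1.63) and Cdkn1a (0.76). Cdkn1b fell from 28.9 ± 1.56 to 9.42 ± 1.53 CPM. Amino acid stress genes, which include serine synthesis, had 7 lower and 1 higher of 14 (1 higher and 8 lower when adjusted over the list alone). The amino acid stress response list had a median log2 fold change of −0.67 and a camera adjusted p of 0.0273 (adjusted p = 0.642 with an estimated correlation). This call was lost without untreated replicate 3 (adjusted p = 0.0958). Psat1, an enzyme of serine synthesis, fell from 333 ± 65 to 153 ± 22 CPM. Shmt2 fell from 198 ± 8.32 to 89 ± 11.3 CPM. Ddit4 rose from 24.8 ± 8.06 to 52.9 ± 8.32 CPM. The p53 response had 5 higher and 3 lower of 16 (5 higher and 3 lower when adjusted over the list alone). The p53 response list had a median log2 fold change of −0.11 and a camera adjusted p of 0.834. Their mean was 0.10, opposite in sign to the median and the test. Pmaip1, a BH3-only protein, rose from 15.7 ± 2.57 to 31.5 ± 5.49 CPM and Zmat3 fell from 164 ± 8.95 to 96.7 ± 7.86 CPM. Glycolysis genes had 5 higher and 4 lower of 20 (5 higher and 4 lower when adjusted over the list alone). The glycolysis list had a median log2 fold change of 0.11 and a camera adjusted p of 0.958. The lactate transporter gene Slc16a3 rose from 19 ± 1.56 to 73.4 ± 12 CPM. Hk2 fell from 233 ± 9.6 to 93.9 ± 13.3 CPM. Cholesterol synthesis genes had 4 higher and 4 lower of 17 (4 higher and 4 lower when adjusted over the list alone). The cholesterol synthesis list had a median log2 fold change of 0.04 and a camera adjusted p of 0.956. Their mean was −0.01, with the sign of the test and opposite to the median. Sqle rose from 81.2 ± 8.24 to 118 ± 3.42 CPM while Ldlr fell from 57.7 ± 13.6 to 34.8 ± 2.45 CPM.

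Among the 8 genes with the largest increases of those at 10 CPM or more after treatment, beside Fgf5 and the Zscan4 and Usp17l copies, Itih5 (chromosome 2, 10153571 to 10256529), a hyaluronan-associated matrix protein, rose from 0.382 ± 0.117 to 11.5 ± 1.32 CPM (log2 fold change 4.84, SE 0.27, edgeR adjusted p = 1.14e-06). Car4, a membrane-bound carbonic anhydrase, rose from 5.43 ± 2.6 to 108 ± 13.1 CPM. The X-linked gene Usp26 rose from 2.44 ± 2.11 to 43.7 ± 0.513 CPM (log2 fold change 4.25, and 5.13 without untreated replicate 3). Of the genes at 10 CPM or more before treatment, the largest of the 8 decreases was that of Inhbb (chromosome 1, 119415465 to 119422248), the beta B subunit of inhibin and activin, which fell from 98.3 ± 34.6 to 0.782 ± 0.363 CPM (log2 fold change −6.91, SE 0.34, edgeR adjusted p = 6.20e-07). The Ras family gene Mras fell from 75.1 ± 10.1 to 0.808 ± 0.122 CPM (log2 fold change −6.51, SE 0.18, edgeR adjusted p = 3.72e-08). Gli2, a transcription factor of the hedgehog pathway, fell from 211 ± 36.1 to 8.24 ± 1.84 CPM. Spp1, the secreted phosphoprotein osteopontin, fell from 314 ± 43.7 to 13.9 ± 1.29 CPM. Emp1 fell from 31.6 ± 2.59 to 0.869 ± 0.185 CPM. Msc fell from 14.8 ± 3.4 to 0.323 ± 0.212 CPM (log2 fold change −5.52, and −6.29 without treated replicate 2). Vwa3b fell from 15.6 ± 0.562 to 1.04 ± 0.376 CPM.

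Over all 15360 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 called 7259 genes (47.3%), 3800 higher and 3459 lower. With a fold change of at least 2 besides, 3251 genes were called, 2259 higher and 992 lower, and with at least 4, 1299, of which 1027 were higher. Of the 30 lists, 14 were called by camera with a preset correlation of 0.01, and with an estimated correlation the calls of naive pluripotency and of the LIF and STAT3 response, which share 2 members, held. The preset test also called 4 to 12 lists in the other 9 splits of the 6 libraries into 3 and 3. Those splits mix the groups unequally and keep part of their difference, so this is no rate of false calls. NaB, the medium and the time in culture changed together in these 2 groups, so no difference can be assigned to one of them.

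**Figure D3:**
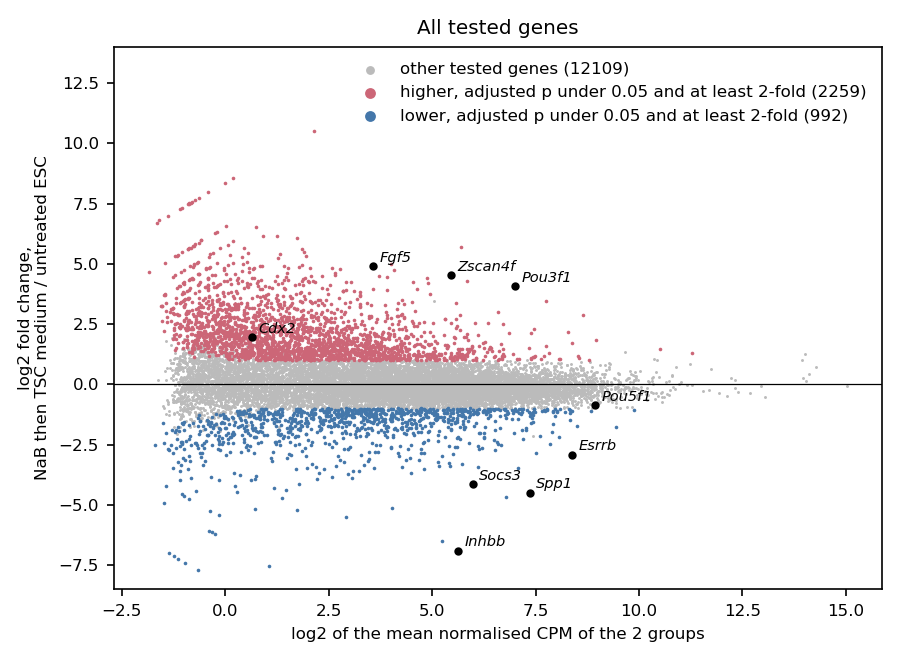
Log2 fold change, NaB then TSC medium over untreated ESCs, against the log2 of the mean normalised CPM of the 2 groups, one point per tested gene. Red points are the 2259 genes that were higher and blue points the 992 genes that were lower at an edgeR adjusted p under 0.05 and at least 2-fold, and grey points are the other tested genes. Slanting rows of points at low CPM are genes with a count of 0 in one group, whose fitted fold changes are no measure of size.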

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

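Leaving out the 2 treated libraries with a high mitochondrial share and leaving out mitochondrial-like genes were chosen after the data were seen. The count of genes past an adjusted p of 0.05 was 7259 and ran from 5641 (without untreated replicate 1) to 8093 (no filter), and the count with 2-fold change was 3251 and ran from 2825 to 3879. Without the 2 high-mitochondrial libraries the first count was 5414, a fit of 1 treated library that is assumed to vary like the untreated ones. Library sizes alone gave 5951 genes, 58.7% of them higher, against 52.3% with TMM. Deviations of same-numbered libraries from their group means had correlations of 0.04, 0.09 and −0.01, and those of other pairs across the groups ran from −0.08 to 0.05. No clear pairing was seen, but with 3 libraries per group it cannot be excluded that the numbers pair them. The replicate block called 7276 genes, 6949 of them shared, and 3186 with 2-fold change, and ended the calls of the cell cycle list (adjusted p = 0.0504) and Tagln (adjusted p = 0.0622) while calling Eomes (0.64, adjusted p = 0.0497). The 135 tested named genes are the sentinel genes and those chosen for the largest changes, which favours stable calls. Members named only for a lost call or because few lay on their side, such as Gata2 and Sall4, are not among them. Apart from the fit with 1 treated library, 121 of the 135 tested named genes kept their call in each fit made and none changed direction with a call. Over those 2021 comparisons 39 calls were lost and 13 gained, and with that fit 52 were lost over 2156. Calls were lost for Cdx2, Hdac1, Hdac2, Msx2, Tagln, Cdx1, Ccn1, Chac1, Crebbp and Nsdhl in some fits, for Aurkb, Snai1, Perp, Ldlr, Trib3 and Wnt7b in the fit with 1 treated library, and gained for Eomes, Gata3, Sox2 and Tfap2c. Among the 30 lists, 27 calls were lost and 22 gained in 480 comparisons, 30 and 22 in 510 with that fit, and none was reversed. The differentiated trophoblast median was 0.92 with library sizes alone (adjusted p = 0.0313), 0.74 without a filter (adjusted p = 0.0488) and 0.79 to 0.94 with a library left out, and became a call in 3 of these 6 fits and with fry (0.89). The trophoblast stem cell median was 0.68 without a filter (adjusted p = 0.0155) and 0.58 to 0.81 with a library left out, and became a call in 2 of these 6 fits and with fry (0.74). Primitive endoderm lost its call with a filter of 1 CPM (−0.34), with limma-voom (−0.37), without the 2 high-mitochondrial libraries (−0.47) and with an estimated correlation (−0.36). General pluripotency (−0.29, −0.29) and neuroectoderm (−1.23, −1.22) lost theirs with limma-voom and with an estimated correlation, and the estimated correlation also ended those of the formative epiblast (1.71) and fibroblast (1.91) lists. The cell cycle list also lost its call without mitochondrial and histone genes (adjusted p = 0.0529) and without the 2 high-mitochondrial libraries (adjusted p = 0.136), the BMP response with limma-voom (adjusted p = 0.0554), the acetyltransferases with a filter of 1 CPM (adjusted p = 0.0611), and the amino acid stress response without the 2 high-mitochondrial libraries (adjusted p = 0.0791). The Wnt response became a call with library sizes alone (adjusted p = 0.0423), without a filter (adjusted p = 0.0178) and with a filter of 1 CPM (adjusted p = 0.0217). The number of lists called was 14, 2 with an estimated correlation and 23 with fry, whose null hypothesis differs. The cause was not tested. Low counts left 17 of 31 differentiated trophoblast genes and, of 20 trophoblast stem cell genes, Elf5 (17 counts, all in treated libraries) untested.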

Other observations

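The interferon list, the chromosome medians, the family sums, the bound on the 2-cell-like medians, the comparisons of 4 fibroblast genes with others and the bound from mitochondrial reads were tests chosen after the result was seen. Ifih1, a sensor of double-stranded RNA, had 0 counts in the untreated and 76 in the treated libraries, at least 27.6-fold higher against a floor of 3 counts over the group, and Isg15 went from 1 to 51 counts, a ratio of 55.6 (95% counting interval 9.53 to 2237). Oasl2 rose by 4.25 on the log2 scale, Cxcl10 by 2.80 and Tlr3 by 1.66, while Stat1 (−0.83), Irf9 (−1.08), Oas2 (−1.52) and Ifitm3 (−1.61) fell. Of 30 interferon-stimulated genes 21 were tested, 8 rose and 4 fell, with a median of 0.59 (camera p = 0.189, p = 0.303 with an estimated correlation). The list was written after Ifih1 and Oasl2 were seen and holds both, so they count among the 8 and weigh on the test. The 9 members too low to test held 42 counts in the untreated and 191 in the treated libraries, and 8 of them had more in the treated ones. A general rise of interferon-stimulated genes, which could explain the rise of Ifih1, stays open as a hypothesis.

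Medians of the 19 autosomes lay between −0.08 and 0.06, that of the X chromosome was 0.14 over 560 genes, and that of the 15 mitochondrial genes was 0.62. The number of splits of the 6 libraries into 3 and 3 is 10, too few for a share under 0.05. The real split called 7259 genes, 3251 with 2-fold change and 14 lists, and the highest of the other splits gave 0, 0 and 12 (4 at the fewest for lists), with 1 of the 10 splits reaching the real value in each case. The other splits mix both groups on each side. The group difference then adds to the spread within a side and part of it stays between sides, so their counts are not those of unchanged libraries.

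The fall of naive and rise of formative epiblast genes was set against GC content and gene length. After a trend of log2 fold change on GC content and length was removed, the formative median was 1.45 and the naive median −1.74, which argues against such a trend as the whole cause, while the trophoblast stem cell median, not called before, went from 0.74 to 0.44. Reads taken up by mitochondrial and mitochondrial-like genes scale all other genes of a library alike, by 0.107 to −0.212 at most on the log2 scale between a treated and an untreated library, and normalisation removes such a factor, so the list medians are no test of it. The change of medium without NaB may have caused the fall, and with 0 libraries of cells in TSC medium without NaB it cannot be told apart from NaB. An effect of NaB itself stays open for the same reason.

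The rise of 2-cell-like genes was set against the division of reads among near-identical copies and against a single library. The summed counts of whole families, which do not depend on how reads were divided, rose by 4.19 on the log2 scale for the Zscan4 and by 4.05 for the Usp17l family between group means, which argues against division as the cause. The lowest median over the 6 fits that leave out a library was 4.03, which argues against one library. A rise in a share of cells and a rise in each cell could not be separated in bulk libraries, and a group in TSC medium without NaB was not part of the comparison.

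The rise of fibroblast markers was set against carry-over of feeder cells, which may differ between media. Fibroblasts express Col3a1, Dcn, Lum and Postn at high levels, and these 4 genes together rose by 0.211 CPM, against a gain of 16.4 CPM for Col1a1, a ratio of 0.0128. Against the gains of Col5a1, Col6a2, Mmp2 and Thy1 the ratio was 0.0316 or less. For these genes and Col1a1 this argues only against carry-over of cells that express the 4 genes at high levels. The 4 were chosen after the result was seen, and no fibroblast library gave an expected ratio or the bound of 0.1. Carry-over of feeder cells is thus not excluded as a source of these rises. For Bgn, Col1a2 and Fbln2 the ratio reached 0.0633. The CPM of the 4 genes in their highest treated library reached 0.178 of a gain, past the bound of 0.1, so carry-over stays open there. Lox, which rose from 0.108 ± 0.096 to only 1.04 ± 0.31 CPM, was not compared with the 4 genes, and carry-over stays open for it too. No biological explanation was tested. Sparc (−0.90), Fn1 (−0.92) and Vim (−2.04) fell, from levels that would hide a small share of fibroblasts.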
